A study of Mus musculus with 3 samples.

How the data were processed

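Xist is the long noncoding RNA that coats 1 X chromosome of female mouse cells and starts its silencing. RNA antisense purification (RAP) recovers an RNA with the chromatin it lies on: biotinylated antisense probes are hybridised to the RNA in the lysate of crosslinked cells, and the genomic DNA that comes down with them is sequenced. Female mouse embryonic stem cells (ESCs), labelled as strain 129SvJae, were grown in 2i and LIF, which hold them in an undifferentiated state, and were moved for 2 or 4 days to the medium that turns them into epiblast-like cells (EpiLCs). The labels name 3 libraries: 1 Xist pulldown on day 2, 1 Xist pulldown on day 4 and 1 input DNA library from day 2. The values analysed here come from the 2 pulldown libraries; no value of the input library on its own was used here.

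Per the submitters' processing notes, the tools were Trim Galore 0.4.1, Bowtie2 2.2.9, SAMtools 1.2, Picard and bedtools, and the genome build was mm9; the role and settings of each are not given in the sources used here. The deposited values are enrichment ratios, 1 per row and library, rounded by the authors to 2 decimals. From the word enrichment and the input library among the samples they are taken to be pulldown over input, but which input served for day 4, and how libraries were scaled to each other, are not given in the sources used here. If the day 2 input was the denominator on both days, its noise is common to both profiles and raises their correlation. Over all rows with a value, the deposited ratio averaged 0.968 on day 2 and 1.01 on day 4, so it behaves as a share of each library: a higher ratio on the X goes with a lower one elsewhere.

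Each file holds 106205 rows of 25 kb at the same positions. The authors' file naming gives windows of 100 kb moved in steps of 25 kb, and the first row of each nuclear chromosome lies where the centre of such a window would. A row is therefore read as the centre of a 100 kb window, so a point of the genome enters 4 successive rows. At chromosome ends the step is shorter and windows may be cut short; this holds for 84 rows, of which 31 had a value, 0 of them on the X. A second deposited column holds a flag of 0 or 1. The flag was 1 in 11776 rows (11.1%), the same rows on both days; the ratio was 0 in all of them and in 0 other rows. Flagged rows were treated as having no value. They made up 40.2% of rows on the X, between 3.59% and 21.0% on the autosomes and 100% on the Y chromosome and the mitochondrial genome; the rule behind the flag is not given in the sources used here. This left 3987 rows on the X and 90442 on the 19 autosomes, called windows below. Positions are mm9, counted from 1. The gene table supplied with the data is of another build and was not used, so no gene is assigned to a window.

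With 1 library per day there is no replicate error, so no p-value is given for a difference between the days or between regions. The files hold no read counts, so the depth is unknown and no counting interval can be given. Quartiles describe the spread over windows, which overlap and are not replicates. Medians and quartiles were computed per chromosome, the autosomes serving as the background of the same library. For the comparison of the days each ratio was divided by the autosomal median of its library, and the log2 of day 4 over day 2 was taken with no pseudocount. Spearman correlations across the X used 1 row in 4, so that windows did not overlap (998 windows on the X and 22598 on autosomes), and were set against 10000 random circular shifts of the profile along the X, as a description of these libraries. Distances were measured from the X window with the highest value of the day, because no mm9 position of the Xist gene was used; comparisons of the days used the highest X window of either day, which was that of day 2. Domains were runs of touching rows above the 90th percentile of X windows of a day; low domains were runs below the 10th percentile.

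The regions named were chosen by a rule fixed before the data were examined: the 3 domains with the highest and the 3 with the lowest mean per day and the 5 highest autosomal windows per day. The 5 Mb bins along the X, the stretch between 110 and 125 Mb and the ends of the X were chosen after the values were seen, as was the decision to leave out flagged rows. Lists of X-linked genes and a count of genes per window had been planned and were not run without an mm9 annotation. The script functions were tested on 50 simulated pairs of profiles over the 3987 X windows: a log2 gain of 1.5 came back with a largest error of 0.0054, 49 of 50 falling trends and 1 of 50 profiles without a trend lay outside the middle 95% of the shifts, and 2 of 50 pairs of independent profiles shared more of their domains than the middle 95% of the shifts. The simulated gain was measured without division by an autosomal median, so that step was not tested. The falling trends were steep, a log2 fall of 1.5 per standard deviation of distance. The simulations therefore do not show that a weak trend would be found. Alternatives covered the overlap of windows, medians against means, thresholds, the anchor, low windows, the scaling between the days and pseudocounts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random seed 20.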

Results

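DNA recovered with Xist was profiled in 1 library from day 2 and 1 library from day 4 of differentiation of female mouse ESCs into EpiLCs, as the ratio of enrichment in 100 kb windows across the genome. Values were deposited for 3987 windows of the X and 90442 windows of the autosomes on both days. Each value below rests on 1 library, its read depth is unknown, and differences between the days have no replicate check.

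The first comparison asked how much more DNA of the X than of the autosomes came down with Xist. The X stood far above every autosome on both days. On day 2 its median enrichment was 10.87 (quartiles 5.37 and 17.64), against 0.38 (0.21 and 0.63) over all autosomal windows, a ratio of 28.6. On day 4 the X median was 16.58 (quartiles 9.07 and 22.3) and the autosomal median 0.29 (0.20 and 0.43), a ratio of 57.2. The X held 4.22% of the windows and 53.7% of the summed enrichment on day 2, and 67.6% of it on day 4.

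Nearly the whole measured X was above background. On day 2, 3958 of the 3987 X windows (99.3%) exceeded the 99th percentile of autosomal windows, which was 1.58. On day 4 all 3987 exceeded it, at 1.04. The lowest X window was 1.07 on day 2 and 1.39 on day 4, which is 2.82 and 4.79 times the autosomal median of the same day. Among autosomes the medians ran from 0.27 on chromosome 3 to 0.60 on chromosome 19 on day 2, and from 0.23 to 0.38 on the same chromosomes on day 4. These figures leave out the flagged rows, 40.2% of the X; with those counted as 0, which was tried after seeing the data, the ratios of medians were 10.6 and 23.6.

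**Figure D1:**
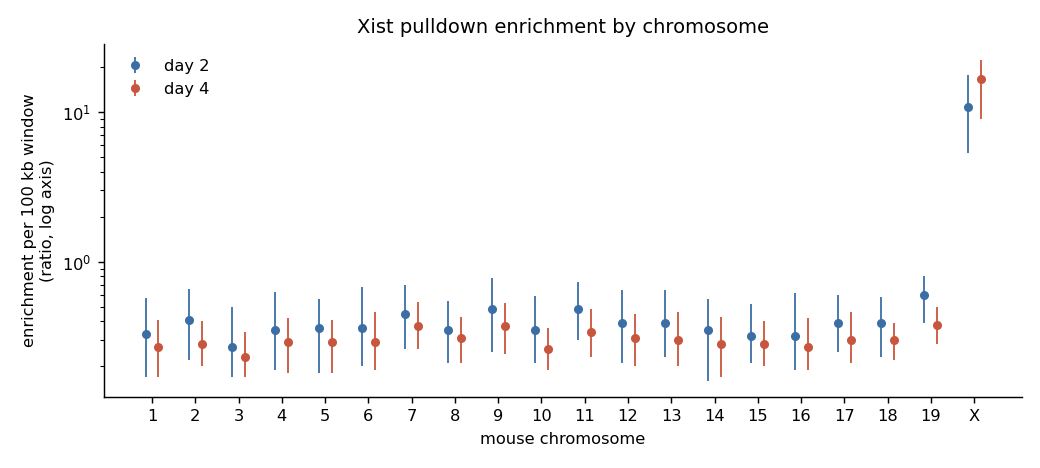
Median enrichment (points) and quartiles (bars) of the windows of each chromosome on day 2 and day 4, on a log axis; windows are not replicates and each day is 1 library. The X medians of 10.87 and 16.58 lie above all autosomal medians, of which the highest is 0.60.

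The second comparison asked how recovery varied with position, and with distance from the strongest site. On day 2 the highest window of the genome was on the X, at 100662501 to 100687500, with an enrichment of 82.67, or 7.61 times the X median. It belonged to a narrow summit of 4 rows, from 100612501 to 100712500, with values between 73.35 and 82.67. The rows next to it were at 35.61 and 38.94. The windows of these 4 rows have 25 kb in common, from 100650001 to 100675000. On day 4 the same 4 rows were at 37.05 to 44.58, and their highest value ranked 21 among X windows.

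On day 4 the highest X window was at 137562501 to 137587500, with 62.9; on day 2 that window had 47.43 and ranked 5. The window at the day 2 summit was 0.512 times as high on day 4 as on day 2 in the deposited ratios, while the window at 137562501 was 1.33 times as high. Each window was picked as the highest of its own day, so the first fold could not exceed the other. The direction of this contrast was therefore fixed by the choice of windows.

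Enrichment did not fall steadily with distance from the day 2 summit. On day 2 the median was 29.6 within 1 Mb of it (63 windows), 18.25 between 1 and 5 Mb, 9.44 between 5 and 10 Mb and 2.85 between 10 and 20 Mb. It was higher again farther out, at 10.02 between 20 and 40 Mb, 14.17 between 40 and 60 Mb and 7.85 beyond 60 Mb. The day 4 medians over the same bins were 25.89, 23.14, 12.18, 3.18, 16.01, 20.12 and 14.43. Across 998 windows that do not overlap, Spearman's rho of enrichment and distance was -0.075 on day 2, measured from the summit of that day. It lay inside the middle of the circular shifts, -0.14 to 0.18. On day 4 rho was 0.059 from the day 4 summit (shifts -0.33 to 0.23) and 0.023 from the day 2 summit.

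The X was divided into stretches of high and low recovery. The 5 Mb bin with the highest median on both days was 95 to 100 Mb, at 26.0 on day 2 and 27.3 on day 4. The longest run of bins under 0.25 of the X median on both days, from 110 to 125 Mb, formed a low stretch: the median of its 274 windows was 2.27 (quartiles 1.96 and 2.77) on day 2 and 2.36 (2.01 and 2.79) on day 4. That is still 5.97 and 8.14 times the autosomal median. Many rows of the stretch were flagged: 132, 93 and 49 of 200 had a value in the bins from 110, 115 and 120 Mb. Bins at 30 to 35 Mb and 50 to 55 Mb, far from the summit, were high on day 2, at 20.2 and 20.3.

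**Figure D2:**
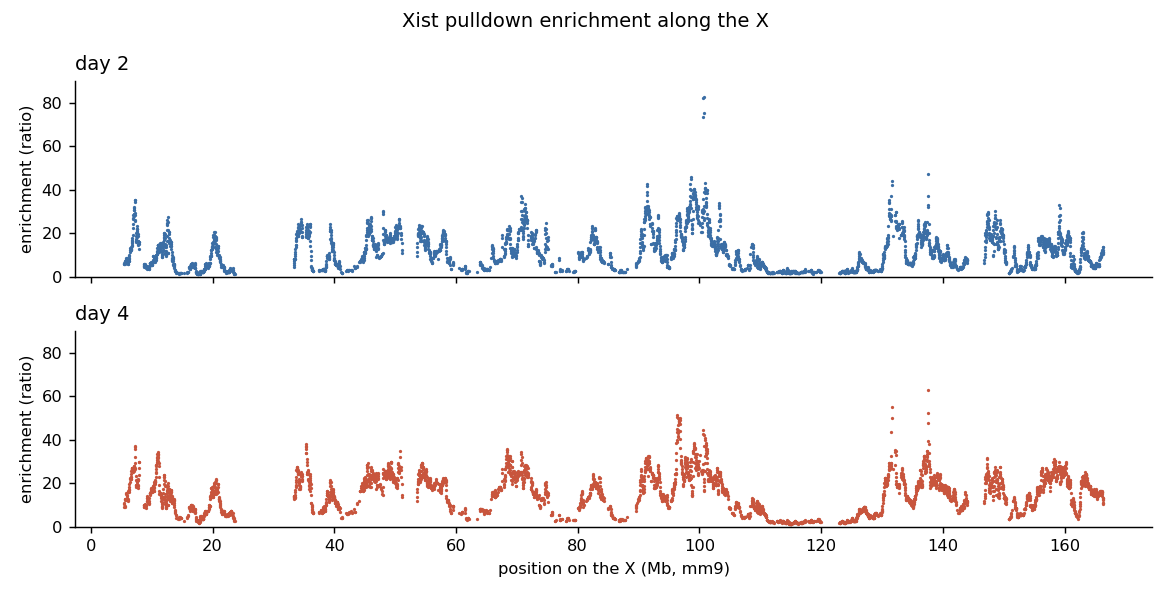
Enrichment ratio of each 100 kb window along the X (mm9, in Mb) on day 2 (upper) and day 4 (lower); gaps are flagged rows without a value. The day 2 summit at 82.67 stands above the rest of its profile, the highest day 4 window is 62.9, and the stretch from 110 to 125 Mb is low on both days.

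The domains above the 90th percentile showed how far the most enriched parts coincided. There were 48 on day 2, above 23.3, and 59 on day 4, above 26.7, with median lengths of 100 kb and 125 kb. The days shared 5.35 Mb of the 14.6 Mb that were in a domain on either day (36.7%); circular shifts gave 5.36% on average, and the middle 95% of them reached 12.7%. Low domains, below the 10th percentile, shared 65.4%, against 5.76% on average and 32.1% at the upper end of the middle 95% of shifts.

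The 3 day 2 domains with the highest mean were at 100387501 to 101337500 (mean 38.0 on day 2 and 30.8 on day 4), 137562501 to 137662500 (35.4 and 50.2) and 98837501 to 99887500 (33.1 and 30.5). On day 4 the first was at 96137501 to 97087500, a 950 kb domain with a mean of 41.0, against 24.7 on day 2. The others were at 100587501 to 100712500 (39.1 on day 4 and 69.9 on day 2) and at 137562501 to 137812500 (37.9 and 23.9). The low domains that ranked lowest by mean were not the same on both days. On day 2 they were at 23612501 to 23637500 (1.09 on day 2 and 2.64 on day 4), 14437501 to 14462500 (1.43 and 3.65) and 23437501 to 23537500 (1.45 and 3.34). On day 4 all 3 lay within the stretch from 110 to 125 Mb, at 115237501 to 115262500 (1.54 on day 4 and 2.48 on day 2), 116787501 to 116812500 (1.63 and 2.05) and 116187501 to 116412500 (1.63 and 1.66). The means of all these low domains were below the 10th percentile of the other day too, which was 2.68 on day 2 and 4.23 on day 4. Their rank among low places differed between the days, and several were single rows.

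The third comparison set day 4 against day 2 along the X. Relative to the autosomal median of each library, enrichment was higher on day 4 in 3904 of 3987 X windows (97.9%). The median log2 ratio was 0.88, a fold of 1.83, with quartiles of 0.51 and 1.24. Autosomal windows had a median log2 ratio of 0.09 and quartiles of -0.29 and 0.45. Of the X windows, 48.1% exceeded the 95th percentile of the autosomal windows, 0.90. Without scaling, the median fold on the X was 1.40 and on the autosomes 0.810, and 82.7% of X windows were higher on day 4. The size of the increase on the X is therefore partly that of the decrease on the autosomes.

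The difference between the days was uneven along the X; folds are relative to the autosomal medians unless stated. All 32 bins of 5 Mb with values had a median above 0, and 12 were over 2-fold higher on day 4; without scaling the median fold was above 1 in 30 of the 32 and above 2 in 3. The bins with the largest differences were at the distal end: the median fold was 2.87 between 160 and 165 Mb and 3.29 beyond 165 Mb. From 160 Mb on, the deposited median went from 8.10 on day 2 to 16.04 on day 4 (243 windows). In the first 20 Mb, where values began only at 5437501, the deposited median went from 7.57 to 12.99. The median fold there was 1.66 without scaling and 2.18 relative to the autosomes. Bins at 40 to 45 Mb, 65 to 70 Mb and 140 to 145 Mb had folds of 2.59, 2.59 and 2.65.

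The smallest differences were at 115 to 120 Mb and 120 to 125 Mb, with folds of 1.29 and 1.31 (93 and 49 of 200 rows with a value). Bins at 145 to 150 Mb and 70 to 75 Mb, both high on day 2, followed with 1.34 and 1.40. Within 1 Mb of the day 2 summit the median fold was 1.27 (0.973 without scaling), and the mean of the 4 summit rows was lower on day 4, by a log2 ratio of -0.52. The summit was picked by its day 2 value, which favours a low fold there. Beyond 60 Mb from the summit the fold was 2.26. The rho of the log2 ratio with distance from the day 2 summit was 0.35, just inside the middle 95% of circular shifts (-0.38 to 0.36).

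**Figure D3:**
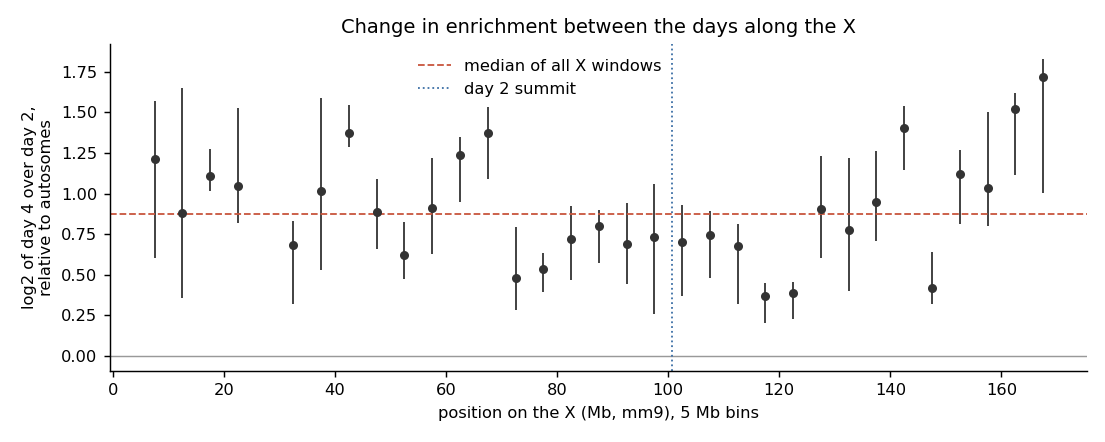
Median (points) and quartiles (bars) of the log2 ratio of day 4 over day 2, each relative to its autosomal median, in 5 Mb bins along the X (mm9); the dashed line is the median of all X windows, 0.88, and the dotted line the day 2 summit. The highest medians are beyond 160 Mb and the lowest between 115 and 125 Mb.

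The order of windows along the X was similar on the 2 days. Spearman's rho between the days was 0.88 across the 998 X windows that do not overlap (the middle 95% of shifts reached 0.36). Across autosomal windows, treated in the same way, rho was 0.87. These correlations are across windows of 1 library per day, windows are not independent replicates, and part of either value may come from a common input, whose values were not used here.

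On the autosomes the 5 highest windows of each day all lay on chromosome 6, between 114362501 and 114637500. The highest, at 114437501 to 114462500, was at 16.72 on day 2 and 11.18 on day 4, against autosomal medians of 0.38 and 0.29.

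**Figure D4:**
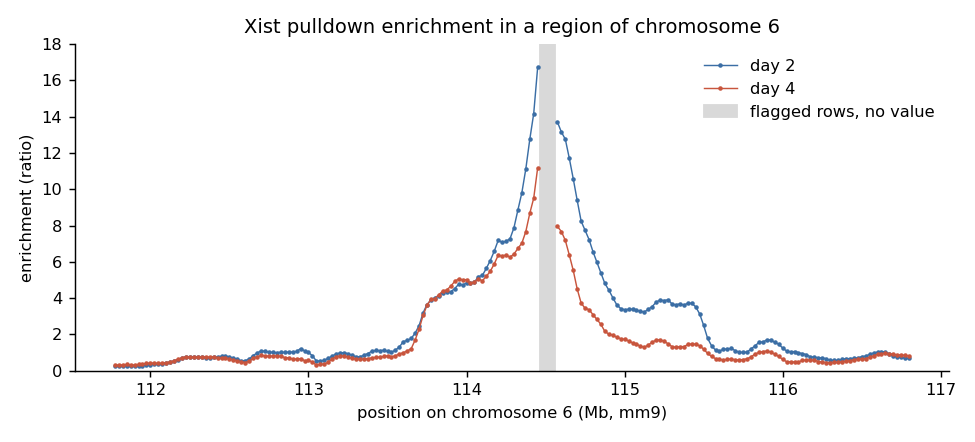
Enrichment ratio of each 100 kb window around the chromosome 6 region (mm9) on day 2 and day 4; the grey band marks 4 flagged rows without a value. Values peak beside the band, at 16.72 on day 2 and 11.18 on day 4, and are lower on both sides, with a shoulder to the right on both days (3.87 on day 2 and 1.62 on day 4 at 750 kb).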

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

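All tests of this part were chosen after the result was seen. A region of chromosome 6 stood out from the autosomes, which served only as background. Its 38 windows, between 113762501 and 114812500, were the only autosomal ones above 10 times the autosomal median on both days, and they held the 5 highest autosomal windows of each day. Its highest window, at 114437501 to 114462500, had an enrichment of 16.72 on day 2 and 11.18 on day 4, which is 44 and 38.6 times the autosomal median. The next 4 rows, 114462501 to 114562500, were flagged and have no value; their windows have the 25 kb from 114500001 to 114525000 in common. Values were lower on both sides: 500 kb to the left of the centre of the flagged rows they were 4.84 on day 2 and 5.02 on day 4, and 500 kb to the right 3.36 and 1.73. The right side held a shoulder on both days, with 3.87 on day 2 and 1.62 on day 4 at 750 kb. The windows of chromosome 6 more than 2 Mb from that centre had medians of 0.35 and 0.28 and highest values of 1.86 and 1.51. Rows above 10 times the median on either day reached from 113712501 to 115287500 on chromosome 6; on other autosomes they were 2 adjacent rows of chromosome 4, at 98837501 to 98887500, with 3.81 and 3.92 on day 2 and 1.30 and 1.41 on day 4.

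Capture of a single off-target site without its surroundings is argued against by the rows 500 kb away, of which the lower was 3.36 on day 2, above the 1.86 that was the highest value more than 2 Mb away. The same gain between the days as on the X is argued against too: the upper quartile of the region's log2 ratio was 0.39 (median 0.22, 38 windows), below the lower quartile of the X, 0.51. These 38 windows had to be high on both days, which leaves out rows that were lower on day 4; over all 59 windows from 113712501 to 115287500 the upper quartile was 0.32 and the median -0.19. The sides of that span had median log2 ratios of 0.32 (30 windows to the left) and -0.71 (29 to the right). Low gains occurred on parts of the X as well, where 7.98% of windows were below the 0.22 of the 38 windows. The X median was 0.35 within 1 Mb of the day 2 summit and 0.37 at 115 to 120 Mb, the lowest of the 32 bins. What stays open is an off-target site recovered with the chromatin around it, Xist sequence or RNA at this place in these cells, and a contact with the X; no value here separates these, and no biological explanation was tested beyond the difference between the days.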

How the results depend on the processing

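Of 96 alternative values for 11 results, 79 kept their direction and stayed within the spread over 5 Mb blocks of the X (for shares, the exact binomial interval of windows that do not overlap). All settings that took windows without overlap at another offset were among the 79. They draw on the same or overlapping windows as the main values and could differ little, so the count of 79 overstates how much was tested. Counting flagged rows as 0, chosen after seeing the data, gave ratios of X to autosomal medians of 10.6 on day 2 and 23.6 on day 4, and shares of X windows above the autosomal 99th percentile of 59.4% and 59.8%, because 40.2% of X rows then are 0. The day 2 share was 100% with the lowest 5% of windows left out or at the 90th autosomal percentile, and 99.9% at the 95th. These settings do not test the share: a lower percentile can only raise it, and the lowest 5% include the 29 X windows below the threshold. On day 4 the share was 100% already, so the lower percentiles, counted among the 79, had to give the same. The rho of enrichment with distance on day 2, -0.075, turned to 0.061 from the day 4 summit and to 0.10 without windows within 5 Mb. The windows within 5 Mb had the highest day 2 medians of the distance bins, 29.6 and 18.25. The negative sign therefore rested on the windows around the summit. Why the sign changed with the day 4 summit was not tested. The median log2 ratio of the days on the X, 0.88, was 0.49 with no scaling. Scaling to the X median, which removes the mean change by construction, gave -0.12, and -0.18 with the 5 Mb around the summit left out; the share of X windows higher on day 4 was 82.7%, 41.4% and 37.6% under these 3 scalings and 98.9% without windows within 5 Mb of the summit. The log2 ratio had a rho of -0.32 with distance to the nearer chromosome end, an alternative added later that measures distance the other way. This rho lay inside the middle 95% of circular shifts, -0.35 to 0.38. The rho between the days stayed between 0.86 and 0.89 and the shared part of high domains between 29.4% and 44.8%. Leaving out windows with a value of 0 removed none, and other settings for gene lists and gene density were not run, like those results, because no mm9 annotation was used. No paired analysis was possible because each day has 1 library, and for the same reason none could be left out. Without read counts it is unknown how deep each window was covered, so small differences between low windows cannot be weighed.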

Other observations

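The tests of the 110 to 125 Mb stretch, of level outside it and of the narrow summit were chosen after the result was seen. The rho with distance was fixed before the data were examined and its reading as an explanation after; the test of flagged rows was written before its result. The autosomal background was structured. On day 2 the autosomes with the highest medians were chromosomes 19 (0.60), 11 (0.48), 9 (0.48) and 7 (0.45), and on day 4 they were 19 (0.38), 7 (0.37), 9 (0.37) and 11 (0.34). Chromosome 3 had the lowest median on both days, 0.27 and 0.23. The autosomal quartiles were 3-fold apart on day 2 and 2.15-fold apart on day 4, and those of the X 3.28-fold and 2.46-fold. On the X, levels were lower where more rows within 500 kb were flagged, with a rho of -0.50 on day 2 and -0.53 on day 4.

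The gain on the X was uneven, and a candidate explanation is a compression of the scale on day 4. The rho between the log2 ratio and the mean log2 level of both days was -0.46 on autosomes and -0.33 on the X. With the 110 to 125 Mb stretch left out it was -0.51 on the X (931 windows). A narrower spread on day 4, present on autosomes and X, fixes the sign of this rho, so it decides nothing on either. Compression cannot account for the stretch from 110 to 125 Mb, lowest on both days, whose log2 ratio had an upper quartile of 0.71, below the X median of 0.88. Distance from the day 2 summit (rho 0.35, shifts up to 0.36) and flagged rows nearby (rho 0.10, shifts -0.21 to 0.21) cannot be told apart from no relation, because neither left the range of the shifts. Whether the narrower spread on day 4 is a property of the pulldowns or a more even spread of the RNA stays open. There was 1 library per day, of unknown depth.

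The day 2 summit had 4 raised rows (above 1.8 times the median within 500 kb), the number that a source within 1 step of 25 kb gives with these windows. A source that crosses a step enters 5 or more, and the adjacent rows, at 35.61 and 38.94, were above the flank median of 27.2, so a slightly longer source stays open. The 4 rows stood 2.88 times over the median of their flanks within 1 Mb on day 2 and 1.61 times on day 4. A hypothesis is that the summit is the gene of the RNA that was pulled down, where new transcripts lie. Probes that capture the DNA of the gene itself may give the same shape, and the 1.61 of day 4 cannot be told apart between them, because both predict a narrow summit on both days and no control probe library was used here.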
